A study of Danio rerio with 8 samples.

How the data were processed

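RNA sequencing measured transcripts in kdrl-positive cells of zebrafish embryos at 28 hours post fertilization, with 4 libraries from sf3b1 mutants and 4 from siblings. Per the labels' protocols, RNA was extracted with a column kit, ribosomal RNA was depleted with RiboGone, and libraries were made with the SMARTer Stranded kit. Per the labels' design text, they were sequenced on an Illumina instrument. The submitters' processing notes name Trim Galore, STAR 2.4.2a, Picard and Cufflinks 2.2.1 and the genome build GRCz10. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, whole numbers with no normalization by the authors as far as the values show. Ribosomal depletion of total RNA keeps unspliced RNA and transcripts without a poly(A) tail, and a count per gene does not tell these from spliced RNA.

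The table has 31901 genes, of which 4867 were counted in no library. A symbol from a table of Ensembl names was found for 29178, and 2723 had none. Genes without a symbol held 12.9% to 19.6% of a library's counts. Some symbols are zebrafish names in lower case, and others are in capitals after the human gene and can be shared by paralogues: 10080 of the tested genes have the latter. A value given with an identifier is that of this identifier alone, and other identifiers of the same symbol often did not pass. Library totals ran from 10035886 to 13277963 counts. Positions in the genome are not given, since the gene table at hand describes another assembly. The sources name no molecular identifiers, so PCR copies may be among the counts.

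Mutant and sibling libraries were compared with edgeR 4.0.16 (glmQLFit with robust=TRUE and glmQLFTest, group as the only factor) in R 4.3.3, after TMM normalization and filterByExpr (smallest count 10, smallest total 15), which left 18289 genes. P-values were adjusted after Benjamini and Hochberg, and adjusted p under 0.05 counted as passing. Every adjusted p of a gene in the text comes from this test. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use the TMM library sizes. The design, the 29 gene lists, the rule for named genes and the alternatives listed below were set before the data were examined, apart from those said to be added later.

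The rule for named genes took sf3b1, then the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 3, no overlap between the groups' values and a symbol that is no clone or accession name, then up to 4 genes with the smallest p from each list. As written it leaves out symbols that start with capitals, so it was applied as written and, by a choice made after the table was seen, again with capital symbols admitted. Further genes named in the text were chosen after their values were seen: kdrl, cdh5, cdkn1a, BAX, TRIM8, MYB, RUNX1, MECOM, SPI1, gfi1aa, itga2b, hbae3, HBE1, gata1a, drl, VLDLR, PSAT1, SHMT2, SLC7A5, HSPA5, hsp70l, dnajb1a, FOSB, IER5L, MYC, ECT2, CCNB1, HNRNPU, CLK1, RBM5, ISL1, SHH, flt1, PLCG1, clec14a, plvapb, ushbp1, icam3, CLDN5, HEY1, RBPJ, ephb4a, MRC1, BMPER, tgfb1b, SMG6, RBM8A, RNPS1, UNC45B, RYR1, PAX3, TFEC, atp1a1a.5, PAX2, the second identifiers of ZFP36L1 and FN1, SSB, coil, smn1, GEMIN5, snapc1b and the genes of the symbol families. List members were matched by symbol without regard to case, and otherwise by the symbol without its paralogue letter, a step chosen after the symbols but before the values were seen.

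For each list, the members passing over all genes and those adjusted over the list alone were counted. The lists were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and again with an estimated correlation, both adjusted over the 29 lists, and fry was run as a second test. Shares of counts were compared with exact two-sided permutation tests. Bootstrap intervals of list medians resampled the genes of a list as if independent, so they leave out the spread between libraries. The script was tested on simulated data drawn from the means and library sizes of these samples. There it called 30 of 99 genes with a simulated log2 fold change of 1 (30.3%) and 64 of 98 with 2 (65.3%) among 17203 genes, and 5 of 99 calls (5.05%) were false. With no gene changed it made 0 calls among 17204 genes. The changed genes were drawn only from those above a lowest mean count.

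Replicates of each group were compared first. Chi-square statistics per degree of freedom between pairs of the same group were 13.99 to 47.24, so no pair agreed within sampling noise and each library counted as 1 sample. The first principal component (36.7% of the variance) separated mutants from siblings, and the second (22.6%) set apart mutant replicate 4 and sibling replicate 2.

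The alternatives were RLE size factors, total counts only, upper-quartile normalization, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, robust=FALSE, the replicate number as a block, mitochondrially encoded and hemoglobin genes left out, and each library left out in turn. After the data were seen, fits without both mutant replicate 4 and sibling replicate 2 and without the highest-count gene were added. Splicing itself, such as retained introns, was not analysed here, since the table gives a single count per gene. Some genes that the rule selects or that fall in small counts are not reported here.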

Results

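Endothelial cells were studied in zebrafish embryos at 28 hours post fertilization. The cells were isolated as kdrl-positive. kdrl encodes a VEGF receptor of blood vessel and endocardial endothelium. The deposited counts are labelled kdrlgfp, so the sort may have followed a GFP reporter of kdrl and not kdrl itself. Total RNA of 4 samples from sf3b1 mutants and 4 samples from siblings was sequenced after removal of ribosomal RNA. sf3b1 encodes a core subunit of the U2 snRNP, the particle that recognises the branch point of introns during splicing. The comparison of mutant with sibling cells asks which transcripts differ in endothelial cells when this splicing factor is mutated. The mutant libraries held 13277963, 12590630, 10035886 and 12149213 counts, and the sibling libraries 10307076, 10742406, 12002020 and 12237885. The labels give neither the allele, nor the genotype of the siblings, nor the number of embryos per library. They do not say whether the replicates came from separate clutches either, so the p-values measure only the spread between these samples, which may be technical. Expression levels are given in CPM, counts scaled to library size, as mean ± SD over 4 libraries, and log2 fold changes of mutant over sibling are given ± SE.

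The transcript of the mutated gene, SF3B1 (ENSDARG00000056138), was lower in the mutants. It stood at 162.8 ± 17.7 CPM in mutant and 297.3 ± 60.5 CPM in sibling libraries, which is 0.547 of the sibling level. The log2 fold change was -0.87 ± 0.166 (adjusted p = 0.00168, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and every mutant library lay below every sibling library. The isolation marker kdrl (ENSDARG00000105215) stood at 1137 ± 396 CPM in mutants and 801.3 ± 212 CPM in siblings (log2 fold change 0.50 ± 0.241, adjusted p = 0.167). It passed the threshold when mutant replicate 1 was left out, with a log2 fold change of 0.68. The junction gene cdh5 (ENSDARG00000075549) stood at 804.5 ± 235 and 832.3 ± 254 CPM (log2 fold change -0.05 ± 0.238, adjusted p = 0.919), and the sign of this small difference turned with the scaling.

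The mutant libraries of sorted cells had higher transcripts of spliceosome genes and of p53 targets, lists that passed also with an estimated correlation. Many stress response, mitotic, histone, blood cell and neural genes were lower, but none of these lists passed with an estimated correlation (adjusted p = 0.0625 to 0.369 with an estimated correlation). With fry, which does not compare a list with other genes, all of these lists passed (fry adjusted p = 0.000551 to 0.0209). Of the 10 heat shock genes in the planned list, 4 were higher, while that list, which also holds immediate early genes, was not shifted (camera adjusted p = 0.385). Of 18289 genes tested, 3902 (21.3%) passed an adjusted p of 0.05, 1814 of them higher and 2088 lower in the mutants. A change of at least 2-fold was reached by 2435 of these, 1150 higher and 1285 lower. In 4879 genes (26.7%) the mutant and sibling values did not overlap, where chance gives 2.86%. Upper-quartile normalization gave 2062 higher and 1806 lower genes. Mutant replicate 4 and sibling replicate 2 stood apart from the other libraries of their groups in the principal components, and without both of them 4054 genes passed, 1899 higher and 2155 lower.

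Under the rule for named genes as written, which leaves out capital symbols, the largest rises included genes of the machinery that transcribes small nuclear RNAs. snapc4 (ENSDARG00000067673), a subunit of the complex that activates these promoters, rose from 31.49 ± 0.895 to 329.7 ± 26.4 CPM (log2 fold change 3.39 ± 0.143, adjusted p = 8.51e-09). ice1 (ENSDARG00000058461), of the little elongation complex, rose from 26.11 ± 4.96 to 259.3 ± 17.5 CPM. brf2 (ENSDARG00000002060), an initiation factor of RNA polymerase III, rose with a log2 fold change of 3.64 ± 0.449. The other rises under the rule for named genes were those of mat2al (5.45 ± 0.713), ptges3l (4 ± 0.639), the finTRIM gene ftr34 (3.93 ± 0.537), the heat shock gene hspa1b (3.84 ± 0.364), isg15 (3.51 ± 0.404), rpz5 (3.40 ± 0.316) and the carbonic anhydrase gene ca4a (3.39 ± 0.478). With symbols in capitals admitted, a choice made after the table was seen, RSPO1 (6.32 ± 0.704), PDE6D (4.98 ± 0.598), LNX1 (4.50 ± 0.456), ATXN1 (ENSDARG00000060862, 4.23 ± 0.25), HSPA8 (ENSDARG00000037403, 4.2 ± 0.55) and RBL2 (4.05 ± 0.229) entered the 10 largest rises. They displaced snapc4, ice1, brf2, isg15, rpz5 and ca4a. RSPO1, which encodes a secreted activator of Wnt signalling, stood at 18.58 ± 5.98 CPM in mutants and 0.2212 ± 0.257 CPM in siblings.

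The largest falls included leukocyte and neural genes. mrc1b (ENSDARG00000038822), a mannose receptor gene, fell from 20.14 ± 7.18 to 0.9303 ± 0.82 CPM (log2 fold change -4.42 ± 0.674, adjusted p = 0.000366). The neutrophil protease gene npsn (ENSDARG00000010423) fell from 315 ± 39.8 to 23.89 ± 25.4 CPM. The neural transcription factor gene pou3f2a (-4.11 ± 0.657), the neuronal adhesion gene cntn2 (-3.28 ± 0.467) and the neuronal splicing regulator nova1 (-3.02 ± 0.414) fell as well. The other falls under the rule were those of bicc2 (-4.26 ± 0.501), the intermediate filament gene synm (-3.51 ± 0.392), sesn2 (-3.37 ± 0.314), the complement gene c7a (-3.30 ± 0.748) and hprt1l (-3.29 ± 0.339). With capital symbols admitted, SLC25A47 (-4.60 ± 0.671), CPA1 (-4.26 ± 0.529), GNMT (-3.87 ± 0.63), EPX (-3.71 ± 0.914) and LRRTM1 (-3.59 ± 0.497) were among the 10 largest falls. In that ranking cntn2, nova1, synm, sesn2, c7a and hprt1l were no longer among them. The call of EPX was lost on leaving out any of 6 libraries, the exceptions being mutant replicates 1 and 4, with log2 fold changes of -5.17 to -3.36.

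**Figure D1:**
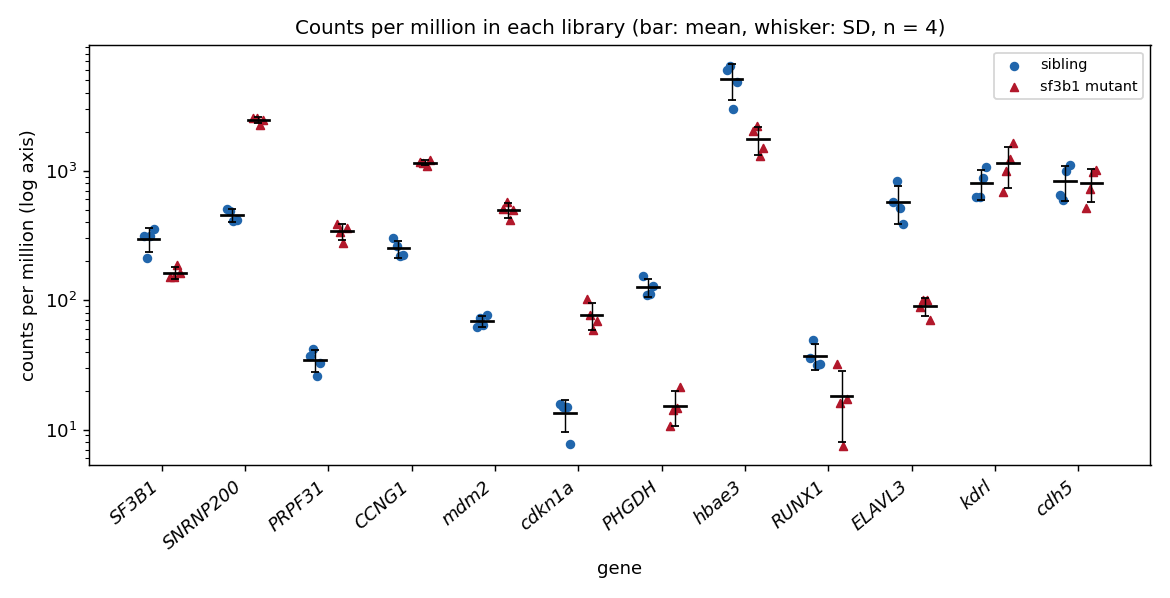
CPM on a log axis for 12 genes in each of the 4 sibling and 4 sf3b1 mutant libraries, with the mean as a bar and the SD as whiskers. SNRNP200 averaged 2462 CPM in mutants and 454.1 CPM in siblings, while cdh5 averaged 804.5 and 832.3 CPM.

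Genes of the spliceosome rose together in the mutants, while SF3B1 itself fell. Of 44 genes tested from the list of spliceosome genes outside the U2 snRNP, 34 rose, 1 fell and 9 did not pass (35 higher and 1 lower adjusted over the list alone), with a median fold of 2.71. The helicase gene SNRNP200 (ENSDARG00000077536) rose from 454.1 ± 51 to 2462 ± 133 CPM (log2 fold change 2.44 ± 0.128). Its partners in the U4/U6.U5 particle rose as well, with log2 fold changes of 2.67 ± 0.145 for the GTPase gene EFTUD2, 2.74 ± 0.148 for PRPF3 and 3.31 ± 0.182 for PRPF31, the latter from 34.32 ± 6.74 to 339 ± 46 CPM. The list as a whole was shifted upward against all other genes (camera adjusted p = 3.27e-44, and adjusted p = 0.00667 with an estimated correlation).

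Of 25 U2 snRNP genes, 16 rose, 1 fell and 8 did not pass (17 and 2 adjusted over the list alone), with a median fold of 1.85. SF3A3 rose by a log2 fold change of 2.29 ± 0.161, from 63.2 ± 10.4 to 309.7 ± 30.5 CPM, and SF3A2 by 1.98 ± 0.203. HTATSF1 (2.55 ± 0.204) and SF3B6 (1.87 ± 0.162), whose products bind SF3B1 in the particle, rose too. The single gene that fell was SF3B1. This list was shifted upward (camera adjusted p = 1.85e-11, and adjusted p = 0.0328 with an estimated correlation). Of 45 genes for SR proteins, hnRNPs and their partners, which set splice site choice, 14 rose, 4 fell and 27 did not pass, with the same counts adjusted over the list alone. srrm2 (1.24 ± 0.158), HNRNPAB (ENSDARG00000099865, 1.25 ± 0.184) and HNRNPK (ENSDARG00000007034, 0.97 ± 0.151) rose, and the kinase gene CLK2 (ENSDARG00000062954, -1.20 ± 0.19) and HNRNPU (ENSDARG00000015206, -0.97 ± 0.172) fell. The calls of CLK1 (-0.75 ± 0.227) and RBM5 (-0.58 ± 0.192) were lost on leaving out single libraries, with -0.89 to -0.66 and -0.71 to -0.42. The shift of that list (camera adjusted p = 0.0408) did not pass with an estimated correlation (adjusted p = 0.447 with an estimated correlation), nor without mutant replicate 4, sibling replicate 3 or sibling replicate 4, nor without both libraries that stood apart.

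Of 16 genes of nonsense-mediated decay, the pathway that removes transcripts with early stop codons, 5 rose and 3 fell (6 and 5 adjusted over the list alone). EIF4A3 (1.59 ± 0.179), GSPT1 (0.61 ± 0.12), ETF1 (0.72 ± 0.148), RBM8A (0.71 ± 0.191) and RNPS1 (1.5 ± 0.476) rose, and UPF3B (-1.17 ± 0.217) and SMG6 (-0.54 ± 0.169) were among those that fell. The list as a whole was not shifted (camera adjusted p = 0.509). The calls of RNPS1, SMG6 and RBM8A were lost on leaving out single libraries, where their log2 fold changes stayed within 1.21 to 2.08, -0.63 to -0.44 and 0.61 to 0.77.

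Transcripts of p53 targets rose. mdm2, a ubiquitin ligase gene, increased from 68.7 ± 6.69 to 496.8 ± 63.6 CPM (2.85 ± 0.151), and CCNG1 from 250.8 ± 37.5 to 1149 ± 49.9 CPM (2.2 ± 0.138). The caspase gene casp8 rose by 3.06 ± 0.233. Of the other members, named after their values were seen, the cell cycle inhibitor gene cdkn1a rose by 2.53 ± 0.257 and the apoptosis gene BAX by 0.96 ± 0.202. Of 36 genes tested, 15 rose, 2 fell and 19 did not pass (16 and 2 adjusted over the list alone). The 2 that fell were sesn2 (-3.37 ± 0.314) and TRIM8 (ENSDARG00000060729, -0.87 ± 0.238), the latter not passing without mutant replicate 2, sibling replicate 1 or sibling replicate 4 (-1.09 to -0.75). The list was shifted upward (camera adjusted p = 3.54e-11, and adjusted p = 0.00925 with an estimated correlation).

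Of 39 genes of the integrated stress and unfolded protein responses, 20 fell, 1 rose and 18 did not pass (24 and 1 adjusted over the list alone). The transcription factor genes atf4a (-1.16 ± 0.126), atf5b (-1.95 ± 0.226) and DDIT3 (-1.34 ± 0.173) fell. The serine synthesis gene PHGDH fell from 125.2 ± 19.9 to 15.21 ± 4.55 CPM (-3.04 ± 0.227). PSAT1 and SHMT2, of serine and glycine metabolism, fell by 1.21 ± 0.252 and 1.40 ± 0.198 on the log2 scale, and the amino acid transporter gene SLC7A5 fell by 1.89 ± 0.295. The single riser was VLDLR (1.08 ± 0.274). The chaperone gene HSPA5 stood at 3260 ± 451 and 4202 ± 592 CPM (-0.37 ± 0.137, adjusted p = 0.0719), and it passed without mutant replicate 4, with -0.45. The list was shifted downward (camera adjusted p = 3.48e-08) but not with an estimated correlation (adjusted p = 0.132 with an estimated correlation).

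Of 45 immediate early and heat shock genes, which tissue dissociation can induce, 5 rose, 4 fell and 36 did not pass, with the same counts adjusted over the list alone and no shift of the list (camera adjusted p = 0.385). On leaving out single libraries, 4 to 7 rose and 3 to 7 fell. The risers were FOSB (0.72 ± 0.232) and the chaperone genes HSPA8 (ENSDARG00000037403, 4.2 ± 0.55), HSPB1 (2.31 ± 0.332), hsp90aa1.1 (2.2 ± 0.266) and dnajb1a (0.96 ± 0.235). The more abundant identifier of HSPA8 (ENSDARG00000068992) stood at 6493 ± 603 and 5611 ± 399 CPM (0.21 ± 0.113, adjusted p = 0.219). The RNA decay factor gene ZFP36L1 fell at both identifiers (ENSDARG00000021443, -2.24 ± 0.233, and ENSDARG00000016154, -0.90 ± 0.156), and IER5L (-0.79 ± 0.175) and MYC (ENSDARG00000045695, -0.77 ± 0.259) fell too. The calls of FOSB and MYC were lost on leaving out single libraries, with 0.54 to 0.92 and -0.95 to -0.55. The heat shock gene hsp70l stood at 2637 ± 840 and 1074 ± 682 CPM (1.29 ± 0.552, adjusted p = 0.151), and it passed without sibling replicate 4, with 0.97.

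Of 55 genes of the G2 phase and mitosis, 25 fell, 2 rose and 28 did not pass (27 and 2 adjusted over the list alone). The checkpoint kinase gene bub1 (-1.19 ± 0.148), the topoisomerase gene TOP2A (-1.13 ± 0.142), the phosphatase gene cdc25b (-1.30 ± 0.186) and mki67 (-0.98 ± 0.137) fell. The 2 that rose were ECT2 (1.14 ± 0.224) and CCNB1 (0.65 ± 0.21), the latter not passing on leaving out any of 6 libraries, the exceptions being mutant replicate 3 and sibling replicate 1 (0.54 to 0.78). The list was shifted downward (camera adjusted p = 1.4e-05), but not with an estimated correlation (adjusted p = 0.25 with an estimated correlation). Of 51 genes of S phase and DNA replication, 8 rose and 10 fell (10 and 11 adjusted over the list alone), with no shift of the list (camera adjusted p = 0.674). On leaving out single libraries, 5 to 11 rose and 4 to 9 fell. ORC1 (1.21 ± 0.172), MCM6 (ENSDARG00000057683, 1.14 ± 0.194) and MCM3 (1.09 ± 0.198), which license replication origins, rose, while the nucleotide synthesis gene TK1 fell (-2.06 ± 0.229). The median of this list was 0.104 and its mean -0.00465, so they differed in sign.

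Of 29 histone genes, 21 fell and 8 did not pass (23 lower adjusted over the list alone), with a median fold of 0.36. histh1l1 (-1.45 ± 0.152), histh1l3 (-1.91 ± 0.218) and hist2h3ca1 (-1.54 ± 0.173) fell. Histone genes lie in near-identical copies among which counts can be split, so the values of single genes are uncertain. The list was shifted downward (camera adjusted p = 1.21e-15), but not with an estimated correlation (adjusted p = 0.0625 with an estimated correlation).

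Endothelial identity genes as a group were not shifted. Of 32 pan-endothelial genes, 5 rose, 4 fell and 23 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.301). On leaving out single libraries, 4 to 8 rose and 1 to 5 fell. mmrn2a rose from 43.96 ± 12.7 to 168.6 ± 49.6 CPM (1.94 ± 0.242), and mmrn2b (0.96 ± 0.2), the water channel gene AQP8 (1.08 ± 0.232), clec14a (0.93 ± 0.2) and plvapb (0.81 ± 0.239) rose too. The transcription factor gene sox18 fell to 84.13 ± 25.1 CPM (-1.14 ± 0.214), as did ushbp1 (-0.76 ± 0.22), icam3 (-1.23 ± 0.355) and CLDN5 (ENSDARG00000043716, -0.60 ± 0.191). The calls of plvapb, ushbp1, icam3 and CLDN5 were lost on leaving out single libraries, with log2 fold changes of 0.63 to 1.05, -0.98 to -0.63, -1.46 to -0.97 and -0.72 to -0.48. Without mutant replicate 1 the list as a whole passed upward.

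Of 32 arterial and Notch genes, 5 rose and 1 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.193), and on leaving out single libraries 1 to 5 rose and 0 to 4 fell. TBX20 (2.28 ± 0.569), the Notch ligand genes jag1b (0.91 ± 0.247) and dlc (1.37 ± 0.392), EFNB2 (ENSDARG00000020164, 0.65 ± 0.195) and HEY1 (0.79 ± 0.251) rose, and RBPJ (ENSDARG00000052091, -1.25 ± 0.427) fell. Except for that of TBX20, these calls were lost on leaving out 1 or more of the single libraries, with ranges of 0.73 to 1.02 for jag1b, 1.07 to 1.77 for dlc, 0.46 to 0.76 for EFNB2, 0.66 to 0.93 for HEY1 and -1.52 to -0.94 for RBPJ. Of 23 venous and lymphatic genes, 2 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.722). The endocytic adaptor gene DAB2 rose from 168.9 ± 36.1 to 482.3 ± 30.9 CPM (1.51 ± 0.156) and the venous transcription factor gene NR2F1 fell (ENSDARG00000052695, -1.28 ± 0.223). ephb4a (0.47 ± 0.153), il13ra2 (-1.09 ± 0.325) and MRC1 (-0.94 ± 0.295) passed with all libraries but not on leaving out single ones (0.40 to 0.53, -1.27 to -0.86 and -1.29 to -0.71), and sox18 was the remaining faller. The median of the venous list was 0.00986 and its mean -0.117, while its test pointed downward.

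Of 50 genes of VEGF signalling and sprouting, 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.439), and on leaving out single libraries 5 to 8 rose and 2 to 6 fell. RSPO1, the adhesion gene MCAM (1.05 ± 0.172), the peptide ligand gene APLN (1.23 ± 0.221) and the VEGF receptor gene flt1 (1.29 ± 0.292) rose, and a fibronectin gene, FN1 (ENSDARG00000006526), fell from 257.6 ± 61.3 to 90.33 ± 27.5 CPM (-1.51 ± 0.223). The other fallers were FN1 at its second identifier (ENSDARG00000019815, -1.03 ± 0.186), klf2a and PLCG1 (-0.52 ± 0.138), the latter not passing without mutant replicate 2 (-0.51). Of 21 endocardial and valve genes, 3 rose and 1 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.88), and on leaving out single libraries 2 to 3 rose and 0 to 3 fell. HAPLN1 rose at both of its identifiers (ENSDARG00000068516, 1.55 ± 0.281, and ENSDARG00000102395, 2.82 ± 0.717). GATA6 (1.22 ± 0.414) and klf2a (-0.84 ± 0.282) passed with all libraries but not without most single libraries (leave-one-out ranges 0.89 to 1.61 and -1.18 to -0.64). The median of this list was -0.0372 and its mean 0.012, and its test pointed upward.

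Of 44 TGF-beta and BMP genes, 13 fell, 3 rose and 28 did not pass, with the same counts adjusted over the list alone. The signal transducer gene SMAD3 (ENSDARG00000036096, -1.15 ± 0.159) and the repressor gene skib (-1.69 ± 0.181) fell. SMAD4 (ENSDARG00000012649, 1.49 ± 0.234), BMPER (1.95 ± 0.338) and tgfb1b (1.03 ± 0.27) rose, the latter not without mutant replicate 3 (0.75). The list was not shifted with all libraries (camera adjusted p = 0.128), but it passed downward without sibling replicate 1 and without sibling replicate 2.

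Of 26 genes of hemogenic endothelium and blood stem cells, 11 fell, 2 rose and 13 did not pass (11 and 3 adjusted over the list alone). On leaving out single libraries, 9 to 11 fell and 2 to 5 rose. The shift of the list (camera adjusted p = 0.0472) did not pass with an estimated correlation (adjusted p = 0.159 with an estimated correlation), nor without any of 5 single libraries, nor under 3 other settings. il6r (-1.68 ± 0.224), RASGRP3 (-0.95 ± 0.149), TGFBR2 (ENSDARG00000059363, -1.68 ± 0.295) and MECOM (-1.15 ± 0.214) fell, and the lymphoid transcription factor gene IKZF1 (1.67 ± 0.268) and the repressor gene gfi1aa (2.99 ± 0.708) rose. RUNX1, the transcription factor gene of the hemogenic program, stood at 18.23 ± 10.2 CPM in mutants and 37.09 ± 8.33 CPM in siblings (-1.02 ± 0.345, adjusted p = 0.0478). Leaving out any library but mutant replicate 1 ended its call, and the log2 fold changes ranged from -1.44 to -0.76. The progenitor gene MYB stood at 117.8 ± 24.4 and 93.12 ± 18 CPM (0.34 ± 0.188, adjusted p = 0.236). In the same libraries, 17 of 26 myeloid genes, some of which this list holds, and 15 of 25 erythroid genes were lower, though neither list passed with an estimated correlation (adjusted p = 0.0625 and adjusted p = 0.369 with an estimated correlation).

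Hemoglobin genes made up 0.445% ± 0.0603 of the counts in mutants and 1.43% ± 0.379 in siblings (SD, n = 4; exact permutation p = 0.0286, two-sided, the smallest this design allows; Benjamini-Hochberg adjusted p = 0.0572 over 6 measures). Of 25 erythroid genes, 15 fell and 1 rose (19 and 2 adjusted over the list alone). The globin genes hbbe3 (-1.42 ± 0.143) and hbae1.3 (-2.29 ± 0.253) and the heme synthesis gene UROD (-1.65 ± 0.186) fell, and hbae3 fell from 5076 ± 1550 to 1758 ± 435 CPM (-1.53 ± 0.231). The single riser was drl (1.71 ± 0.236), and the erythroid transcription factor gene gata1a stood at 51.67 ± 17.3 and 31.05 ± 9.46 CPM (0.74 ± 0.286, adjusted p = 0.0831). gata1a passed upward without mutant replicate 4, with 0.95. Of 26 myeloid genes, 17 fell and none rose, with the same counts adjusted over the list alone. The lysozyme gene lyz fell from 9.949 ± 2.87 to 0.6086 ± 0.214 CPM (-4.01 ± 0.546), and the macrophage receptor gene csf1ra (-2.21 ± 0.291) and srgn (-2.2 ± 0.308) fell as well. Both lists were shifted downward (camera adjusted p = 1.55e-10 and 2.47e-10), but not with an estimated correlation (adjusted p = 0.369 for the erythroid and adjusted p = 0.0625 for the myeloid list with an estimated correlation).

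Of 40 neural genes, 16 fell and 1, ISL1 (1.67 ± 0.38), rose (18 and 1 adjusted over the list alone). The neuronal RNA binding protein gene ELAVL3 fell from 576.9 ± 187 to 89.49 ± 13.8 CPM (-2.69 ± 0.216), and PAX6 (ENSDARG00000103379, -1.36 ± 0.228) and NCAM1 (ENSDARG00000056181, -1.73 ± 0.278) fell too. Of 36 notochord, hatching gland and mesenchyme genes, 10 fell and 1, SHH (ENSDARG00000038867, 2.76 ± 0.797), rose, with the same counts adjusted over the list alone. SHH did not pass without mutant replicate 2 or sibling replicate 4 (2.33 to 3.18). The collagen genes COL1A1 (-1.88 ± 0.171) and COL1A2 (-1.54 ± 0.151) and the growth factor receptor genes PDGFRA (-2.68 ± 0.308) and PDGFRB (-2.36 ± 0.287) fell. Both lists were shifted downward (camera adjusted p = 1.46e-06 and 0.000205), but not with an estimated correlation (adjusted p = 0.145 and adjusted p = 0.447 with an estimated correlation).

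Of 43 epidermal and periderm genes, 3 fell and none rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.742). The faller held by the list alone was pfn1 (-1.09 ± 0.184). The calls of krt18a.1 (-0.55 ± 0.155) and ELF3 (-1.06 ± 0.355) were lost on leaving out single libraries, with -0.67 to -0.47 and -1.37 to -0.82. Of 50 skeletal muscle and somite genes, 3 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.959). Without mutant replicate 4, 12 of them rose, and 2 to 3 without any other library. PAX7 fell at both identifiers (ENSDARG00000070818, -2.19 ± 0.293, and ENSDARG00000100398, -1.55 ± 0.369) as did ENO3 (-1.65 ± 0.266), and TNNT3 (ENSDARG00000068457, 0.99 ± 0.222) and UNC45B (1.43 ± 0.36) rose. The calls of RYR1 (ENSDARG00000011422, 1.37 ± 0.431) and PAX3 (ENSDARG00000010192, -0.94 ± 0.284) were lost on leaving out single libraries, with 1.03 to 1.57 and -1.11 to -0.75. The median of the muscle list was 0.361 and its mean 0.19, while its test pointed downward.

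Of 27 neural crest and pigment genes, 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0514), among them SOX9 (ENSDARG00000003293, -1.77 ± 0.222) and TFAP2A (-1.59 ± 0.303), which fell. The calls of gch2 (-2.41 ± 0.678), TFAP2E (-1.51 ± 0.493) and TFEC (1.09 ± 0.357) were lost on leaving out single libraries, with -3.10 to -1.91, -1.75 to -1.34 and 0.83 to 1.49. Leaving out mutant replicate 1, sibling replicate 1 or sibling replicate 2 carried this list past the threshold, as did RLE size factors, total counts only, upper-quartile normalization, no filter on low counts and leaving out the highest-count gene. Of 20 cardiomyocyte genes, 2 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.128), and the list passed downward without mutant replicate 1. The calcium pump gene atp2a2a fell (-0.85 ± 0.196). The troponin genes TNNI1 (ENSDARG00000000474, 3.50 ± 1.08) and TNNT2 (-2.52 ± 0.712) were called in opposite directions, and both calls were lost on leaving out single libraries (3.07 to 4.27 and -3.11 to -2.12). Of 27 genes of pronephros, gut and liver, 3 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.674), and LRP2 (-1.35 ± 0.206) and PAX8 (-1.91 ± 0.34) fell. SLC20A1 fell at ENSDARG00000020114 (-1.39 ± 0.246) and rose at ENSDARG00000010641 (0.88 ± 0.16). The calls of GATA6 (1.22 ± 0.414), PAX2 (ENSDARG00000032578, -2.26 ± 0.66) and atp1a1a.5 (1.41 ± 0.464) were lost on leaving out single libraries, the latter 2 with -2.48 to -1.85 and 1.19 to 1.53. Of 23 interferon and innate immune genes, 1 rose and 2 fell (1 and 0 adjusted over the list alone), and the list was not shifted. The riser was isg15 (3.51 ± 0.404), which the p53 list also holds. The calls of irf3 (-2.50 ± 0.768) and irf1b (-0.74 ± 0.251) were lost on leaving out any of 6 single libraries, with -3.04 to -2.08 and -0.89 to -0.49, the latter end without sibling replicate 3. The medians of the epidermal, endocardial, interferon and pronephros lists changed sign under upper-quartile normalization.

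Genes with a mitochondrially encoded symbol made up 0.912% ± 0.133 of the counts in mutants and 0.531% ± 0.0929 in siblings (SD, n = 4, exact permutation p = 0.0286, two-sided, adjusted p = 0.0572). Mitochondrial genes without such a symbol would not be in this share. Of 13 mitochondrially encoded genes, 6 rose and 7 did not pass (8 higher adjusted over the list alone), among them MT-CYB (1.1 ± 0.17), MT-CO3 (0.85 ± 0.135) and MT-ND4 (0.96 ± 0.18). Of 77 cytoplasmic ribosomal protein genes, 22 fell, 2 rose and 53 did not pass (28 and 2 adjusted over the list alone). RPL12 (-1.17 ± 0.182) and rps20 (-0.88 ± 0.129) fell, and the 2 that rose were the related genes rps27l (1.91 ± 0.23), which the p53 list also holds, and RPL7L1 (1.19 ± 0.194). The mitochondrial list was shifted upward and the ribosomal list downward (camera adjusted p = 1e-04 and 0.000124), but not with an estimated correlation (adjusted p = 0.447 and adjusted p = 0.515 with an estimated correlation). Without mutant replicate 2 or mutant replicate 3, 12 and 14 ribosomal protein genes fell.

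**Figure D2:**
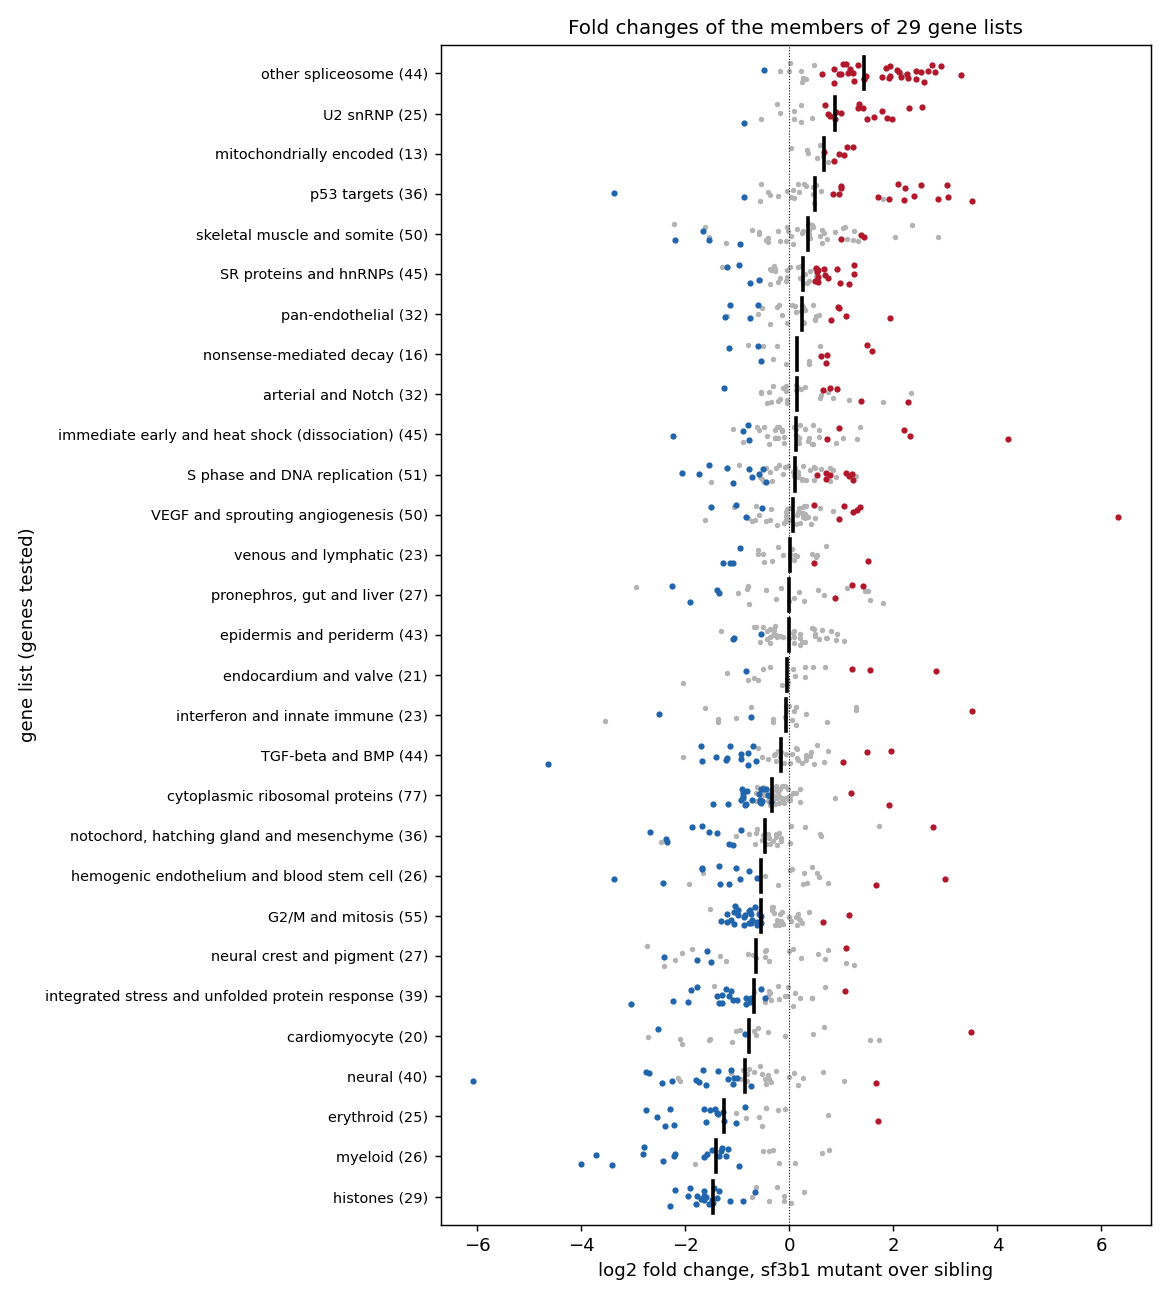
Log2 fold change of mutant over sibling (horizontal axis) for each gene tested in the 29 lists, ordered by their median (black bar), with genes that passed the adjusted p in red where higher and blue where lower, and the others in grey. The medians run from -1.47 for the histones to 1.44 for the spliceosome genes outside the U2 snRNP.

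Of the 29 lists, 14 passed with the preset correlation of camera, and 3 of these passed with an estimated correlation: the U2 snRNP, the other spliceosome genes and the p53 targets. The same 14 lists passed with fry. Symbols shared by paralogues and by copies of a gene limit what the value of a single identifier shows. The strand setting of the counting is not given in the sources used here, so counts of overlapping and antisense genes cannot be told apart from their partners.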

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

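The tests of chance over other splits and of library scaling were chosen only after the results were seen, as was the fit without the highest-count gene. The 8 libraries can be split into 4 and 4 in 35 ways, and 1 of the 35 splits, the real one, gave as many as 3902 genes. The highest of the other splits gave 0 genes with edgeR, the single tool run on the splits, and 1 of 35 is the smallest share this design allows. At an unadjusted p under 0.05, the real split gave 5969 genes and the highest other 1366. Every other split puts mutants and siblings into the same group, so a real difference widens the spread within its groups. The counts of the other splits are therefore not the level that chance alone would give.

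Many erythroid, myeloid and neural genes fell in cells sorted for kdrl, a marker of another cell type. If the mutant sorts held fewer cells of every other type, epidermal genes would have fallen like neural ones. The epidermal median exceeded the neural median by 0.844 (bootstrap 95% interval 0.416 to 1.22, over genes and not libraries). Medians of the cardiomyocyte (-0.764), neural crest (-0.636) and notochord (-0.475) lists were negative too. Those of the epidermal, pronephros and muscle lists stood at -0.00637, -0.00438 and 0.361. The lists thus did not fall alike, but fewer cells of several other types remain possible. The 6 scalings tried do not account for the fall of the erythroid, myeloid and neural genes, as the highest of their 3 list medians was -0.787. These scalings moved the median of all genes by 0.0675 at most, so a larger error of scaling was not tested. The most abundant markers were far from the floor, with hbbe3 at 1769 ± 171 CPM in mutants and 4731 ± 864 CPM in siblings and ELAVL3 at 89.49 and 576.9 CPM, and 2 of the 26 myeloid and 1 of the 25 erythroid genes also stand in an endothelial or hemogenic list. A lower share of blood and neural cells or of their free RNA in the mutant sorts, and lower expression of these genes in sorted cells, remain open, since both may follow from the genotype.

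Spliceosome genes rose together in the mutants. The 6 scalings tried, which include leaving out the highest-count gene, do not account for this, as the lowest median of the 2 spliceosome lists was 0.879. These scalings moved the median of all genes by 0.0675 at most, so a larger error of scaling was not tested. Expression level does not account for the rise either. The median of 1.44 for the spliceosome genes outside the U2 snRNP lay at percentile 100 of random lists matched on expression. The medians of those random lists ran from -0.535 to 0.385. A candidate explanation is a biological one, that transcripts of the splicing machinery increase when SF3B1 is mutated. The lists were set before the data were examined, but this explanation was not tested in other samples. Whether spliced or unspliced RNA of these genes rose stays open, since the counts do not tell them apart.

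Of 10 heat shock genes in the immediate early and heat shock list, 4 passed upward and none downward (median 1.17, camera p = 4.49e-06, and p = 0.0815 with an estimated correlation). The heat shock gene hspa1b (3.84 ± 0.364) is not in that list. The prediction was that immediate early genes would have risen as well if the stress of dissociation and sorting were the cause. Of 35 tested, 1 rose and 4 fell. The heat shock median exceeded the immediate early median by 1.31 (bootstrap 95% interval 0.764 to 2.41, over genes and not libraries). Cells of both groups were sorted, and whether both kinds of genes respond to that stress alike was not tested. The comparison therefore cannot decide whether that stress had a part. A difference in temperature between the groups may be at work, as may the genotype, and neither was tested.

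Single libraries stood far from the other 3 of their group in 23 of 458 groups examined. The nominal rate of the rule would give about 22.9, so the flags as a set show no excess over it. Most of the genes examined were chosen by their values, so that rate may not hold for them. Mutant replicate 4, which also stood apart in the principal components, held 134 CPM of EPX (others 7.42 to 21.7), 121 CPM of sox18 (67.7 to 75.8), 24.2 CPM of ELF3 (11 to 13.2), 6.66 CPM of PDGFRB (14.8 to 16.3), 3.37 CPM of the thrombocyte and stem cell gene itga2b (0 to 0.16) and 241 CPM of the globin gene HBE1 (ENSDARG00000115405, others 274 to 279). It also held 0.0822 CPM of PAX2 (3.07 to 3.68). Without it, itga2b fell by 6.65 on the log2 scale, against -3.36 ± 1.05 with all libraries. Mutant replicate 3 held 16.1 CPM of mat2al (36.7 to 39.6), 82.8 CPM of HSPA8 (236 to 266) and 29.3 CPM of MYC (44.6 to 46.5). Mutant replicate 2 held 36.7 CPM of SMAD3 (40.7 to 40.8) and 31.1 CPM of TRIM8 (45.1 to 46.5). Mutant replicate 1 held 126 CPM of clec14a (163 to 168) and 550 CPM of POLR2B (507 to 513).

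Among the siblings, replicate 1 held 83.4 CPM of PRPF3 (others 70.9 to 71.5), 26.5 CPM of IKZF1 (12.3 to 14.4) and 201 CPM of MCM6 (106 to 122). Sibling replicate 2 held 73 CPM of SF3B6 (50.8 to 54), 49.4 CPM of clec14a (89.4 to 95.3) and 273 CPM of SPI1 (105 to 134). Sibling replicate 3 held 61.7 CPM of CLK2 (78.6 to 81) and 255 CPM of sox18 (159 to 165). Sibling replicate 4 held 7.79 CPM of cdkn1a (14.9 to 15.6).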

How the results depend on the processing

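The fit without both mutant replicate 4 and sibling replicate 2 and the fit without the highest-count gene were chosen after the data were seen. The number of changed genes stayed within 2921 (without mutant replicate 2) and 4808 (DESeq2) over all alternatives. Between 73.3% and 99.9% of the 3902 genes passed in the same direction under each alternative, and 0 passed in the opposite direction under any of them. Leaving out single libraries gave 2921 to 3897 genes, 1305 to 1804 higher and 1616 to 2093 lower. SF3B1 stayed lower and past the threshold under every alternative, and its log2 fold change was -1.02 to -0.78 on leaving out single libraries. Upper-quartile normalization shifted the median of all genes by 0.0675 and made 53.3% of the changed genes higher ones, against 46.5%. With camera's estimated correlation 3 of 29 lists passed, against 14 with the preset one. The cause of that loss was not tested, but a higher correlation alone does not account for all of it. The hemogenic list had an estimated correlation of -0.00674, below the preset 0.01, yet its camera adjusted p went from 0.0472 to 0.159. The p53 list had 0.0152, and its camera adjusted p went from 3.54e-11 to 0.00925. Over the other alternatives 12 to 17 lists passed. The list of hemogenic endothelium genes did not pass under the CPM filter, limma-voom or upper-quartile normalization. The difference of cdh5, which did not pass, was 0.0217 under upper-quartile normalization and -0.20 to 0.12 on leaving out single libraries; the cause was not tested. Of the named genes that passed, 15 (without mutant replicate 4) to 39 (without mutant replicate 2) lost their call on leaving out a library, and 0 to 12 under another normalization, filter or tool.

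With the replicate number as a replicate block, 3782 genes passed, 1746 higher and 2036 lower, and 15 lists. There was no sign that the numbers pair the samples, though this check cannot exclude it. Libraries of the same number correlated at -0.0393 to 0.0534 in their deviations from the group means. Of 8 libraries, 2 correlated best with their own number. With 4 libraries per group at 10035886 to 13277963 counts, simulated changes of 2-fold were called in 30.3% of genes. The simulation changed far fewer genes than passed here (99 and 98 of 17203, against 3902 of 18289), which makes the adjustment stricter. That share is therefore not the power of the comparison itself, though a gene that does not pass may still differ by 2-fold (4808 genes passed with DESeq2).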

Other observations

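The symbol families, the list of small nuclear RNA genes and that of the minor spliceosome were chosen for testing only after the table was seen. Of 31 genes of RNA polymerases, whose symbols begin with polr, 15 rose and 1 fell (median 0.98, camera adjusted p = 1.42e-07 over 279 families, and adjusted p = 0.355 with an estimated correlation). Among them were POLR2B (1.36 ± 0.122) of RNA polymerase II, POLR1B (1.85 ± 0.201) of RNA polymerase I and POLR3B (1.25 ± 0.189) of RNA polymerase III, while POLR2A, which encodes the largest subunit of RNA polymerase II, fell (-0.61 ± 0.126). Of the nuclear genes for mitochondrial ribosomes, 13 of 46 mrpl and 10 of 28 mrps genes rose and none fell, and of those for mitochondrial protein import, 6 of 14 timm and 6 of 10 tomm genes rose. None of these families passed with an estimated correlation (adjusted p = 0.704, adjusted p = 0.704, adjusted p = 0.587 and adjusted p = 0.485 with an estimated correlation). Examples were MRPL12 (1.96 ± 0.324), MRPS33 (3.45 ± 0.438), TIMM8A (2.25 ± 0.373) and TOMM22 (1.33 ± 0.173).

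Of 14 pou transcription factor genes 7 fell and none rose (median -1.06), among them pou3f3b (-2.64 ± 0.255), pou3f1 (-2.44 ± 0.289) and pou3f2a, and of 23 sox genes 5 fell and none rose, among them SOX11 at both identifiers (ENSDARG00000095743, -2.19 ± 0.242, and ENSDARG00000077811, -1.17 ± 0.167). Neither family passed with an estimated correlation (adjusted p = 0.681 and adjusted p = 0.704 with an estimated correlation). Of the neural genes, 16 of 40 were lower in the same libraries. Of 37 kif genes, for kinesin motors, 12 fell and none rose. Of 13 genes whose symbols begin with hspa, 6 rose and none fell (median 0.905, camera adjusted p = 0.000143, and adjusted p = 0.477 with an estimated correlation). In all, 22 families of at least 8 genes passed, 14 higher and 8 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.143 with an estimated correlation).

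snapc4, ice1, brf2 and SSB (3.10 ± 0.153), which act in the making of small nuclear RNAs and RNA polymerase III transcripts, all rose. Of them, snapc4, ice1 and brf2 were among the 10 largest rises under the rule as written, but not with capital symbols admitted. SSB was in neither set. The hypothesis that genes for making small nuclear RNAs rise as a group was tested on a list without these 4 genes. Of its 30 genes 8 rose and 2 fell (median 0.375, camera p = 0.00837 and p = 0.0574 with an estimated correlation), among them coil (2.74 ± 0.203), smn1 (1.54 ± 0.301), GEMIN5 (1.22 ± 0.24) and snapc1b (1.28 ± 0.295). This is consistent with the hypothesis under the preset correlation.

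The hypothesis that genes specific to the minor spliceosome rise like those of the major one was tested on 12 genes, of which 1 passed. Their median was -0.0363 (bootstrap 95% interval -0.201 to 0.34), and it lay 1.5 (bootstrap 95% interval 1.04 to 2.1) below that of 42 spliceosome genes outside the U2 snRNP. The camera p of this list was 0.812. These 12 genes thus did not rise as a set. The 42 genes were not chosen to be specific to the major spliceosome, and the sets were not matched on expression. Whether the rise is restricted to the major spliceosome therefore cannot be told.

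A single gene without a symbol, ENSDARG00000080337, took 14.7% ± 1.17 of the counts in mutants and 11% ± 1.27 in siblings (SD, n = 4; exact permutation p = 0.0286, two-sided, adjusted p = 0.0572). What this gene encodes could not be checked here, and without a symbol it entered no list. With this gene left out, 3902 genes passed, 1882 higher and 2020 lower.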
